A study of Danio rerio with 2 samples.

How the data were processed

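RNA was sequenced from 2 sorted cell populations of zebrafish (Danio rerio) embryos at 20 hours post fertilization. Per the labels' protocols, tails were cut free at the level of somite 3 and dissociated with trypsin and collagenase, fluorescent neural cell bodies were sorted into Trizol, and total RNA was polyA-selected and made into standard Illumina libraries. One library came from the Gal4 driver line 1020st, labelled an olig2+ subpopulation and called the 1020 library below. The other came from a HuC driver, labelled panneuronal and called the HuC library. Each group held 1 library, so no difference between the groups has a replicate check, and no p-value, standard error or false discovery rate is given for one.

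The authors deposited 1 FPKM value (fragments per kilobase of transcript scaled to the number of mapped fragments) per row, and each row carries a chromosome span and no gene name or identifier. The submitters' processing notes name TopHat 1.4.0, Cufflinks 2.1.1, Cuffdiff and the genome build Zv9, without a role or order for each. The annotation, the assembly settings, the filters and whether a row is a gene or an isoform are not given in the sources used here. The spans differ between the libraries: 18 locus strings occur in both. A repeated or overlapping span within a library is frequent, with 70216 rows on 67438 distinct strings in the 1020 library and 49173 rows on 46789 in the HuC library. Starts in the files count from 0, since rows starting at 0 occur, and 1 was added to every start printed here. No Zv9 annotation was used here. Genes could therefore not be named, and olig2, elavl3, the opsins and the 38 gene lists fixed before the data were examined were not analysed here.

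Depth was recovered from the FPKM values themselves. At a given short span, most values are whole multiples of a single amount, the lowest recurring value being 10 of them, so that amount was taken as 1 fragment on a contiguous transcript. Spans of 300 to 600 bp were used where the lowest value recurred at least 2 times and at least 60% of the values were whole to within 0.01 fragments. This left 16336 rows of the 1020 library, of which 85.3% were whole, and 7612 rows of the HuC library, of which 84.1% were whole. A line of the inverse of this amount against span, from 450 bp upward, gave a denominator of 38195621 fragments for the 1020 library and 21878396 for the HuC library, with a largest misfit of 0.0037% and 0.0034%. The denominator is what the authors' FPKM were divided by, which need not equal the number of reads sequenced. On simulated contiguous loci the procedure returned 100% of the denominator put in, at both depths simulated. These loci were built with the same minimum of 10 fragments and a constant length offset. The simulation therefore checks the arithmetic and not whether the deposited rows follow these assumptions. Fragments without molecular identifiers are not independent molecules, so the counting intervals given cover counting error only. In spliced transcripts the length is not given by the span, and their fragments were not recovered.

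FPKM at spans near the read length are inflated and may differ in scale between the libraries. The FPKM of 1 fragment was 1.76 times higher in the HuC library at spans of 300 to 600 bp. At 100 bp it was 2.58 times higher if the lowest value listed there is again 10 fragments. That value rests on 5 rows in the HuC library and was not checked for recurrence or whole multiples. Rows with a span under 300 bp were left out for this reason (7988 of the 1020 library and 1855 of the HuC library), as were 5 longer rows of the 1020 library whose FPKM reached that of 10 fragments on 100 bp. The remaining 62223 and 47318 rows of both libraries were merged into regions wherever they overlapped by at least 1 bp, and FPKM were summed per region and library. A transcript listed in several pieces inside a region is counted once for each piece in this sum. Regions with a row in both libraries and an FPKM of 1 or more in at least 1 of them were compared as log2 of the ratio of (FPKM + 1), 1020 over HuC. The added 1 understates the change of low regions. A region without a row in a library was not taken as 0, since a row is listed only above a minimum, and such regions were counted apart. This departs from the gene-level comparison set out before the data were examined. The span minimum, the merging and the chromosome and span classes were chosen after the files had been seen.

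Regions to be named were the 2 with the highest and the 2 with the lowest ratio among those at FPKM 5 or more in at least 1 library. They replace the 10 named genes per direction of the rule set beforehand, which needs gene names. The region with the highest FPKM in both libraries and the row listed at 0 were added after their values were seen. The median ratio of each chromosome was placed among 10000 random lists of regions of the same size, matched on mean expression in 20 bins. This describes these libraries and is not a test across animals. A simulation at these depths covered 11281 regions with a mean level above FPKM 5. It held counting error only, with 1 row per region and library, capped lengths and no listing minimum. The lengths were spans without the offset of 191 bp (1020) and 193 bp (HuC) that the depth lines gave. Short regions therefore had more simulated fragments, and less counting error, than this offset implies. All 50 regions changed 4-fold and all 50 changed 8-fold were called at 2-fold or more in the right direction. The simulation called 12 of 50 at exactly 2-fold, 0 of 50 at 1.5-fold and 0 unchanged regions. Weaker regions and regions summed from several rows were not simulated. Alternatives were other pseudocounts (0.1 and 5), other FPKM minimums (none and 5), 3 rescalings of the HuC library and the highest row per region. Other span minimums, one-to-one pairs of rows, absent rows taken as 0 and, for the named regions, fragments in place of summed FPKM were added after the data had been seen. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.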

Results

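The transcriptomes of 2 fluorescence-sorted neural populations of the zebrafish spinal cord were measured at 20 hours post fertilization, a stage at which the first spinal circuits become active. The series concerns an opsin, a light-sensing receptor, that acts in the spinal cord. One population was marked by the Gal4 line 1020st and is labelled a subpopulation positive for olig2, a transcription factor of motor neuron and oligodendrocyte progenitors. The other was marked by a HuC driver and is labelled panneuronal; HuC (Elavl3) is an RNA-binding protein of postmitotic neurons. There was 1 library per population. The deposited rows are transcribed loci on the Zv9 build with an FPKM value and no gene name, so the comparison is between regions of the genome.

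The 1020 library held 70216 loci and the HuC library 49173, spread over all 25 chromosomes and over 580 and 471 unplaced sequences. The surplus lay mainly in short loci. Loci with a span under 1000 bp numbered 36186 in the 1020 library and 18741 in the HuC library, while loci of 1000 bp or more numbered 34030 and 30432. The median span was 939 bp and 1828 bp. The FPKM values corresponded to a denominator of 38195621 fragments in the 1020 library and 21878396 in the HuC library, a ratio of 1.75. The lowest recurring value for a locus of 500 bp, taken as 10 fragments, was 0.848 FPKM in the 1020 library and 1.49 FPKM in the HuC library. A locus between these values could thus be listed in the 1020 library alone.

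**Figure D1:**
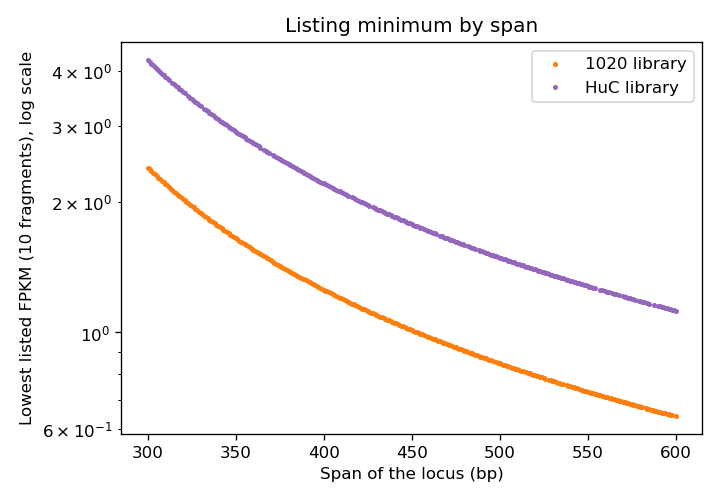
Lowest recurring FPKM (taken as 10 fragments, log scale) of loci against their span in bp, 1 point per span, for the 1020 library (orange) and the HuC library (purple). At every span plotted the HuC minimum lies above that of 1020, for example 2.21 against 1.26 FPKM at 400 bp.

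The first comparison asked how far the same regions were transcribed in both populations. Loci of both libraries fell into 46045 regions, of which 23006 held a locus in both. Of the summed FPKM of the loci compared (300 bp or more), these shared regions carried 93.9% in the 1020 library and 97.0% in the HuC library, and their median FPKM was 4.89 in each. The most abundant shared region was the same in both libraries. It lay on the unplaced sequence Zv9_NA883 from 35131 to 36037, at 12655 FPKM in the 1020 library and 20065 FPKM in the HuC library. The 100 most abundant regions per library were taken among the 22655 counted regions, all listed in both libraries. Regions of a single library could not enter these lists. Of the 100 of the 1020 library, 63 were also among the 100 of the HuC library, where independent lists from the counted regions would share 0.44. Across 22655 counted regions, log2(FPKM + 1) correlated with a Pearson r of 0.87 and a Spearman rho of 0.81. These correlations are across regions, which are not independent replicates.

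The second comparison asked which regions differed in level between the olig2+ subpopulation and the panneuronal population. By their labels the 2 populations may share cells, and this overlap was not measured. Of the counted regions, all listed in both libraries, 18260 (80.6%) lay within 2-fold. Under the alternatives this share ranged from 47.4% with absent rows taken as 0 to 92.5% with a pseudocount of 5. Among the counted regions, 2000 (8.83%) were at least 2-fold higher in the 1020 library and 2395 (10.6%) at least 2-fold higher in the HuC library. At 4-fold or more, 214 regions were higher in the 1020 library and 311 in the HuC library. Among the 1863 regions that reached 50 FPKM in at least 1 library, 258 were at least 2-fold higher in 1020 and 350 in HuC, and at 4-fold 51 and 110. The median log2 ratio of all counted regions was -0.04, with an SD across regions of 0.83. With 1 library per population the spread between animals or sorts is not known, so none of these counts can be set against replicate error. The balance of the 2-fold counts depended on scaling: 54.5% were higher in HuC with the values as deposited and 46.8% when both libraries were set to the same sum.

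The highest ratio belonged to chromosome 2 from 59655491 to 59658554, where the 1020 library had 463 FPKM and the HuC library 1.77 FPKM, a log2 ratio of 7.39. The HuC value came from a locus of 838 bp inside this region and corresponded to 25 fragments, for which the exact 95% Poisson interval was 1.15 to 2.61 FPKM. Among the 22655 counted regions, which leave out those of a single library, this region ranked 103 by FPKM in the 1020 library and 18749 in the HuC library. The next was chromosome 10 from 46496774 to 46499946, at 87.5 FPKM in the 1020 library and 3.19 FPKM in the HuC library, a fold of 21.1 on the same (FPKM + 1) scale. The HuC value there corresponded to 42 fragments, with an interval of 2.30 to 4.32 FPKM.

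By summed FPKM the lowest ratio belonged to chromosome 13 from 8206407 to 8208790, with 4.18 FPKM in the 1020 library and 692 FPKM in the HuC library, a log2 ratio of -7.06. The 1020 library listed this region as 1 locus of 2352 bp, whereas the HuC library listed 3 separate loci of 560, 315 and 385 bp at 112, 310 and 270 FPKM. If the 3 loci are pieces of 1 transcript, which was not tested, the sum counts each in full and overstates the difference. With the highest single locus in place of the sum, the log2 ratio was -5.91. On chromosome 6, from 23188453 to 23193372, the 1020 library had 1.98 FPKM and the HuC library 192 FPKM, a log2 ratio of -6.01. The HuC value there was the sum of 2 overlapping loci with a common start, at 172 and 19.5 FPKM. With the highest single locus its log2 ratio was -5.86, close to that of the region on chromosome 13. The loci of the 2 libraries cover unlike lengths in these 4 regions, and the HuC loci on chromosomes 2 and 10 spanned 838 and 794 bp of 3064 and 3173 bp. With fragments relative to the denominators in place of FPKM, the log2 ratio was 10.2 on chromosome 2, 7.02 on chromosome 10, -3.86 on chromosome 13 and -8.94 on chromosome 6. These are rough values, since they take every locus as contiguous and the main loci behind each were not shown to hold whole fragments, so the order of the 4 regions is not established by them. The genes in these regions were not named here, and whether a region overlaps an exon or an untranslated region was not analysed here.

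**Figure D2:**
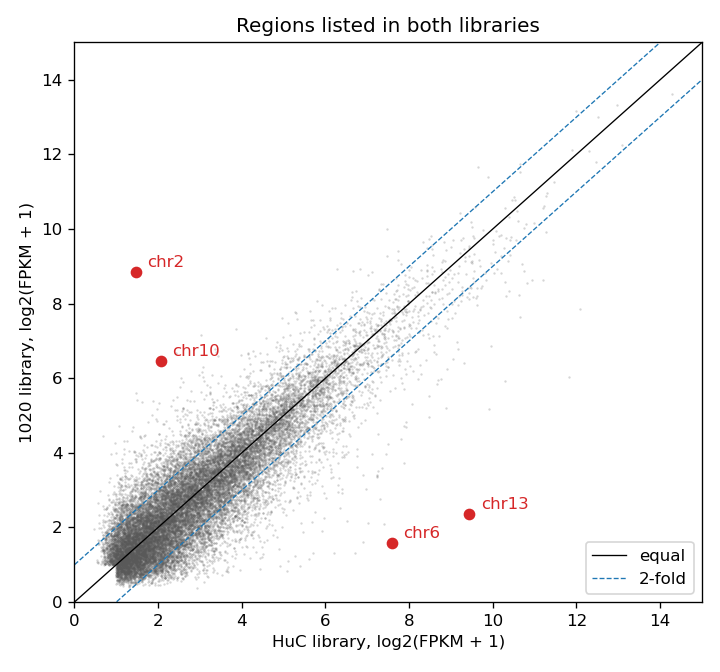
Each grey point is 1 of the 22655 counted regions, with log2(FPKM + 1) in the HuC library on the horizontal axis and in the 1020 library on the vertical axis; the solid line marks equal values and the dashed lines 2-fold. The red points are the regions with the 2 highest ratios (chromosomes 2 and 10) and the 2 lowest (chromosomes 13 and 6), and 80.6% of the regions lie between the dashed lines.

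Regions with a locus in a single library were numerous but mostly weak and short. The 1020 library alone listed 17048 regions, with a median of 1.24 FPKM and a median span of 621 bp. The HuC library alone listed 5991, with a median of 1.63 FPKM and a median span of 677 bp. Shared regions had a median span of 7307 bp. At 5 FPKM or more there were 465 regions in 1020 alone and 329 in HuC alone, and of these 207 and 107 spanned 1000 bp or more. Detectability was evaluated only for regions of 300 to 600 bp, which were taken as contiguous. Longer regions were not evaluated. Among 7396 of these short regions listed in 1020 alone, 1959 (26.5%, 95% Wilson interval 25.494 to 27.505%) would have had an expected 10 fragments or more in the HuC library at the same FPKM. For 278 (3.76%) the expected count was 20 or more. A region with an expected count near the minimum of 10 can miss it by chance. For most of these 7396 short regions, absence from the HuC library was therefore not detectable as a difference. All 2192 such regions of the HuC library would have reached the minimum of the 1020 library at the same FPKM, which its greater depth ensures, and 1297 (59.2%) would have had an expected 20 fragments or more.

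The balance between the libraries changed with the span of a region. Regions of 300 to 1000 bp were at least 2-fold higher in 1020 in 5.04% of 3034 cases and at least 2-fold higher in HuC in 10.8%. Regions of 100000 bp or more were higher in 1020 in 15.9% of 1130 cases and higher in HuC in 7.17%. The median log2 ratio was -0.18 in the shortest class and 0.08 in the longest. The order of the 2 shares in the shortest and in the longest class was the same under all 3 rescalings and both other pseudocounts. With the highest row per region the order also held, but the shares in the longest class lay closer together. They were 11.2% in 1020 and 8.23% in HuC there, and 4.78% and 10.9% in the shortest class. The shares themselves moved with the pseudocount. With 5, the 1020 and HuC shares were 1.25% and 1.71% in the shortest class and 7.96% and 3.89% in the longest. The HuC share was thus higher in the longest class than in the shortest, though below the 1020 share of the longest. With 0.1 they were 9.10% and 21.1% in the shortest and 17.9% and 8.76% in the longest. Among regions at FPKM 5 or more in at least 1 library the rise in the 1020 share was lost: it was 15.4% in the shortest class, lowest at 11.4% in regions of 3000 to 10000 bp, and 16.3% in the longest, while the HuC share was 23.9% in the shortest class and 7.11% in the longest.

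**Figure D3:**
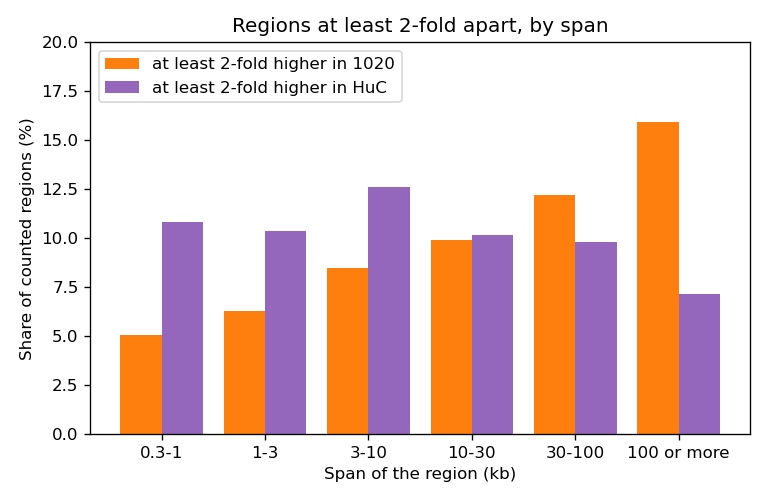
Share of counted regions (%) at least 2-fold higher in the 1020 library (orange bars) or in the HuC library (purple bars), by span of the region in kb. The orange share is 5.04% in the shortest class and 15.9% in the longest; among regions at FPKM 5 or more these are 15.4% and 16.3%.

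Chromosomes differed little. The median log2 ratio of a chromosome ranged from -0.11 among the unplaced sequences to 0.04 on chromosome 2. Chromosomes 2, 5 and 20 had medians above the range of 95% of random lists matched on expression, and chromosomes 3, 19 and the unplaced sequences below it. That made 6 of 26 groups, where 1.3 would be expected if regions were independent. Chromosome 4 had the highest share of single-library regions belonging to 1020, with 985 against 245 in HuC (80.1%), and chromosome 16 the lowest, with 683 against 311 (68.7%). In both libraries the locus on chromosome 10 from 3167715 to 3185565 was listed at 0, the single such value in each, and a listed 0 can also be a failed estimate.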

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

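The tests on stacks, on both restrictions of the span trend together and on population differences were chosen after the result was seen; the others in this part were chosen before it.

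Loci with a span within 1 bp of 100 bp were left out of the comparisons and drew attention as a signal in data that the report does not use. There were 835 of them in the 1020 library and 6 in the HuC library, and they held 98.7% and 71.3% of all summed FPKM. At 100 bp, 1 fragment was worth 26009 FPKM in the 1020 library and 67021 FPKM in the HuC library, so these values are mainly set by the short span. Most of the summed FPKM of each library therefore comes from these loci unless they are removed.

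The 1020 library listed 21043 more rows than the HuC library, and 82.9% of the excess had a span under 1000 bp. Stacks at a single position are argued against as the main source: rows of 110 bp or less, 936 against 20, made up 4.35% of the excess. Stacks spread over more positions would have longer spans and were not tested. Rows under 300 bp numbered 7988 in the 1020 library and 1855 in the HuC library. A deeper 1020 library was tested as a candidate explanation. All rows of 300 to 600 bp with a fragment value in both libraries were taken as contiguous. Rows that were not whole multiples were rounded and kept. The 1020 library had 15263 such rows at the minimum against 7412. After its fragments were thinned to the HuC depth, 6499 reached the minimum, 0.877 times the HuC number (95% counting interval 0.848 to 0.906). No excess was left, but the value lies below the range of 0.9 to 1.1 set beforehand, so how much of the excess comes from depth stays open. A difference between the cell populations was not tested, as each has 1 library.

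Regions of long span had higher 1020 ratios than short ones, with a Spearman rho of 0.103 over all counted regions (the upper bound of the central 95% of permuted orders was 0.014). The higher listing minimum of the HuC library is argued against as the whole cause, since rho was 0.0769 among 9477 regions at FPKM 5 or more in both libraries. Summing more rows in 1020 is likewise argued against, since rho was 0.0854 among 10894 regions with 1 row in each library. With both restrictions together rho was 0.0481 among 3096 regions, against 0.035 in permuted orders, and this lies between the bounds set for it, so their joint effect stays open. A difference between the cell populations may also contribute, but it cannot be told apart from a difference between library preparations with 1 library per group.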

How the results depend on the processing

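The 4 named regions were chosen for their extreme ratios, so their signs could not turn with another pseudocount or the rescalings used. Nor could they turn with the highest row per region, since at most 3 rows were summed per library in each. Only fragments could have turned a sign, and all 28 alternatives kept it, most by construction. With pseudocounts of 0.1 and 5 the log2 ratio was 7.95 and 6.11 on chromosome 2, 4.73 and 3.50 on chromosome 10, -7.34 and -6.25 on chromosome 13, and -6.53 and -4.82 on chromosome 6. With fragments it was 10.2, 7.02, -3.86 and -8.94, which are rough values for the reasons given in the Results. The count of regions at least 2-fold higher in 1020 (2000) stayed within 1.5 times under 9 of 12 alternatives. It was 784 with a pseudocount of 5, 3757 with no span minimum and stacks kept and 12936 with absent rows taken as 0. The count higher in HuC (2395) also stayed within 1.5 times under 9 of 12, and was 3595 with a pseudocount of 0.1, 913 with 5 and 7352 with absent rows taken as 0. At 4-fold, the counts of 214 and 311 became 441 and 667 with a pseudocount of 0.1, 68 and 119 with 5, 1588 and 622 with no span minimum and stacks kept, and 1694 and 1353 with absent rows taken as 0. The share of 2-fold calls higher in HuC, 54.5%, was 42.2% with no span minimum and stacks kept and 36.2% with absent rows taken as 0. Pearson's r (0.87) and Spearman's rho (0.81) became 0.872 and 0.821 without an FPKM filter and 0.788 and 0.696 at FPKM 5 or more. They were 0.873 and 0.79 with the highest row per region, 0.882 and 0.834 from 500 bp and 0.862 and 0.784 in one-to-one pairs. With no span minimum and stacks kept they were 0.527 and 0.753, and with absent rows taken as 0 they were 0.742 and 0.601. Pearson's r was 0.853 with a pseudocount of 0.1 and 0.887 with 5. The pseudocount and the treatment of absent rows act on low regions by construction; the other causes were not tested, and dropping the span minimum was not separated from keeping the stacks. The numbers of shared and single-library regions stayed within 1.5 times under both span minimums tried. Depth limits what can be said of the short regions listed in 1020 alone, and longer ones were not evaluated for this. The alternatives on gene lists, on driver and opsin values and on a quantification status were not run, because the rows carry neither gene names nor a status. No replicate could be left out, and no paired analysis was possible because each group has 1 library.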

Other observations

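The test in this part was chosen before its result was seen. Neighbouring regions resembled each other in their ratio between the olig2+ and the panneuronal libraries. The Pearson r of adjacent counted regions was 0.0769 over 22253 pairs, where the upper bound of the central 95% of orders permuted within chromosomes was 0.015. It was 0.186 for pairs less than 1 kb apart, 0.0748 at 1 to 10 kb, 0.0423 at 10 to 100 kb and -0.00137 in 2416 pairs more than 100 kb apart, where the permuted bound was 0.041. A candidate explanation is that pieces of the same transcribed unit are listed as separate regions, and the absence of the relation beyond 100 kb is consistent with it. Regulation shared by neighbouring genes would also weaken with distance and stays open, since without gene models pieces and neighbours cannot be separated. The same relation between neighbours would make the medians of whole chromosomes vary more than random lists of single regions do.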
